A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

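The data are expression profiles of Saccharomyces cerevisiae strains that carry an alanine substitution in histone H3 (HHT2) or histone H4 (HHF2), together with a control strain for each histone. There were 11 strains: 6 H3 mutants (Q5A, R40A, G44A, R53A, N108A and L109A), 3 H4 mutants (K44A, V81A and Y98A), and the controls hht2-wt and hhf2-wt, which carry unmutated histones per the labels. Each strain was measured in 2 independent cultures, a and b, each on its own array, which gave 22 arrays. Every array was hybridised with labelled RNA of 1 strain and of a common wild-type reference. Per the labels the strain was in Cy3 in culture a and in Cy5 in culture b. The series text describes the opposite order for the first hybridisation. The labels were used, and once turned in this way URA3 was higher, and CAN1, MET17 and TRP1 lower, in the strain than in the reference on all 22 arrays. The opposite order would turn all 22 arrays alike, so this shows only that cultures a and b had opposite dyes. It does not tell which order is right, and the direction of every change rests on the labels.

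According to the deposited protocol text, the arrays were read with an Agilent G2565BA scanner and spots were quantified with ImaGene. The deposited scanner files hold the intensity of each spot and of its local background in both channels, per the file headers, without background subtraction. The deposited value table holds log2 ratios; the protocol text states that the authors applied print-tip loess with a span of 0.4 without background subtraction, followed by a gene-specific dye correction from wild-type self hybridisations. The authors' deposited result table holds log2 fold changes and, in separate columns, a Benjamini-Hochberg corrected p-value for each mutant, made with limma per the protocol text. Tested on the values, those fold changes equal the mutant minus hhf2-wt in the value table for all 9 mutants, H3 mutants included (median absolute difference 6.5e-07 to 7.2e-07 over 6182 probes). Here each mutant was compared with the control of its own histone, and all results start from the scanner intensities. The value table served as an alternative. On 3 of its arrays (hhf2-wt a, hht2-L109A a and hht2-Q5A a) its sign was opposite to the scanner ratios (correlation across genes -0.958 to -0.921, against 0.835 to 0.979 on the other 19 arrays), and those were turned by sign before use.

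Each array has 15552 spots, of which 12776 belong to the 6388 gene probes, each spotted 2 times, and 1872 are external control spots. Background was corrected with normexp and an offset of 50, and the log2 ratio was normalised within each array by global loess in which control spots had weight 0. Ratios were turned to strain over reference and duplicate spots were averaged. Changes are therefore relative to the bulk of genes on the same array. Median signals were 297 to 803 in the strain channel and 285 to 703 in the reference channel, and 50 to 252 probes (strain) and 79 to 476 probes (reference) per array were not above background by 2.6 background SDs. Of the probes, 5326 carried a gene name, 58 of them matched by synonym, and 1062 were left unnamed; a further 0 matched several names. The array files name no genome build, so the R64 gene table was used only for names, chromosomes and neighbours, and 5324 probes were placed on it. For 11 symbols there were 2 probes; these were called in opposite directions in 0 cases and differed in whether they were called in 16 pairs of symbol and mutant.

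Log2 ratios of all 22 arrays were fitted per probe with limma 3.58.1 in R 4.3.3, with a mean for each of the 11 strains and a term for dye orientation, followed by empirical Bayes moderation. This left 10 residual degrees of freedom and a prior of 4.16. A probe counts as changed with a Benjamini-Hochberg adjusted p below 0.05 over the 6388 probes, and every adjusted p given for a gene is from this limma fit. Errors are standard errors of the log2 fold change; their median was 0.07. The fit assumes that all strains vary alike, because 2 cultures alone give a poor estimate. Dye orientation and culture letter coincide in every strain, so this term takes up any shared difference between cultures a and b. In 52 of 55 pairs of strains that difference correlated by over 0.1 across genes (median r 0.387, lowest -0.125), and its source, dye or culture, was not separated. Culture correlation within a strain, across genes, was 0.893 to 0.959. There were 12 comparisons: the 9 mutants against their control, hht2-wt against hhf2-wt, and direct tests of N108A against L109A and of R40A against G44A.

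The fit was tested by simulating changes in the comparison of R53A with hht2-wt. With 100 genes shifted by a log2 change of 0.5, it called 96% of them in data made wholly of noise of the real spread. It called 92% when signals of the real R53A arrays were multiplied before normalisation. At a change of 1 it called 100% in both. The genes with multiplied signals were taken from above the dimmest 25% of probes, so their percentages hold for brighter probes only. With noise the fit made 6 false calls among 6158 unchanged genes and 0 calls in a comparison left unchanged. That noise was independent and equal in all strains, as the fit assumes, so it could not test this assumption. In the data the SD of the difference between the 2 cultures ran from 0.117 (R53A) to 0.217 (G44A).

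There were 33 gene lists, fixed before the data were examined, of which 32 had at least 4 measured genes and were tested; the silent mating loci had 3 probes and were not tested. The lists were histone genes, strain construction and auxotrophic markers, a-specific, alpha-specific and haploid mating genes, subtelomeric seripauperin (PAU) and COS families, genes within 20 kb of a chromosome end, promoter-nucleosome-regulated genes, Gcn4 amino-acid targets, methionine and sulphur genes, purine and one-carbon genes, ribosomal proteins, ribosome biogenesis, genes induced in the environmental stress response, heat shock, proteasome, DNA damage, meiosis and sporulation, Sum1-repressed genes, cell wall integrity, hexose transporters, galactose, glycolysis, oxidative phosphorylation, ergosterol, iron, zinc, phosphate, G1/S, G2/M and M/G1 genes, and chromatin regulators. Camera in limma compared each list with all other genes with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 288 tests of lists and mutants. A list counts as called with an adjusted p below 0.05. An estimated correlation and fry were run as checks; fry tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. With an estimated correlation 0 of the 88 calls were kept, and that p is given beside each call. Counts of changed list members are given over all genes tested and, in parentheses, adjusted over the list alone.

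Correlations between mutants are Pearson r across the log2 fold changes of 6388 probes; genes are not independent replicates, and no p is given. H3 mutants were compared with H4 mutants in 18 pairs, which share no control array. Pairs that share a control were set beside 50 simulated sets of unchanged strains with the same shared control, and were repeated with each mutant against a different control.

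Named genes were drawn from a set given by a rule written before the data were examined. For each mutant these are the 6 genes with the highest and the 6 with the lowest log2 fold change among those past the threshold with both cultures on the same side of both control cultures; up to 3 changed members of each called list; the histone genes and construction markers whatever their test; and the 10 genes called in the same direction in the most mutants. In the direct tests these are the 3 highest and 3 lowest. Genes named outside the rule were chosen after their values were seen. They are IME4 in V81A, MATALPHA1, MATALPHA2, HMRA1, RME1, CIC1, CPR2, SOD1 and CRS5. Mating genes of V81A and Y98A beyond the 3 per list were chosen in the same way. The comparisons, the threshold and the processing alternatives were also chosen before the data were examined. Those alternatives were no background correction, print-tip loess, median centring, leaving out the dimmest 25% of probes, no dye term, the mean of both controls, a trended and robust prior, the authors' value table, only the 4 arrays compared, a further limit of at least 1.7-fold, fry, an estimated correlation, and leaving out each culture in turn. Leaving out the genes of chromosomes I, VIII and XIV, hhf2-wt as the control of the H3 mutants, leaving out each culture for the median correlation, and a different control for each mutant of a pair, were added after seeing the data. Every sample title carries a number whose meaning the labels do not give: 1 for both controls, R53A, L109A and Y98A, and 2 for the other 6 mutants. It was not used here, and for those 6 mutants it differs from that of their control. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.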

Results

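Expression was measured on 22 arrays, with 2 cultures of each of 11 strains, for 6388 probes. The strains carried alanine in place of 1 residue of histone H3 (Q5A, R40A, G44A, R53A, N108A, L109A) or histone H4 (K44A, V81A, Y98A), or an unmutated histone (hht2-wt for H3, hhf2-wt for H4). Each mutant is compared with the control of its own histone, with 2 cultures on each side, and changes are log2 fold changes ± SE. The number of changed genes ran from 4 in L109A to 2958 in G44A, and 5029 probes changed in at least 1 mutant. Among H3 mutants the count went with a number in the sample titles whose meaning the labels do not give: R53A and L109A, which carry 1 as the controls do, changed 43 and 4 genes, and the 4 others, which carry 2, changed 942 to 2958. Number and substitution were not separated there, while Y98A, which carries 1, changed 1956. Between the 2 controls limma called 0 genes, and 0 under each alternative. At an unadjusted limma p below 0.05 there were 70 probes there and 270 in L109A. Both are smaller shares of the 6388 probes than the 0.05 that unchanged strains would give. The log2 fold changes between the controls had an SD of 0.058, under the median SE of 0.068. The spread shared with the other strains may therefore hide small differences in such comparisons.

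**Figure D1:**
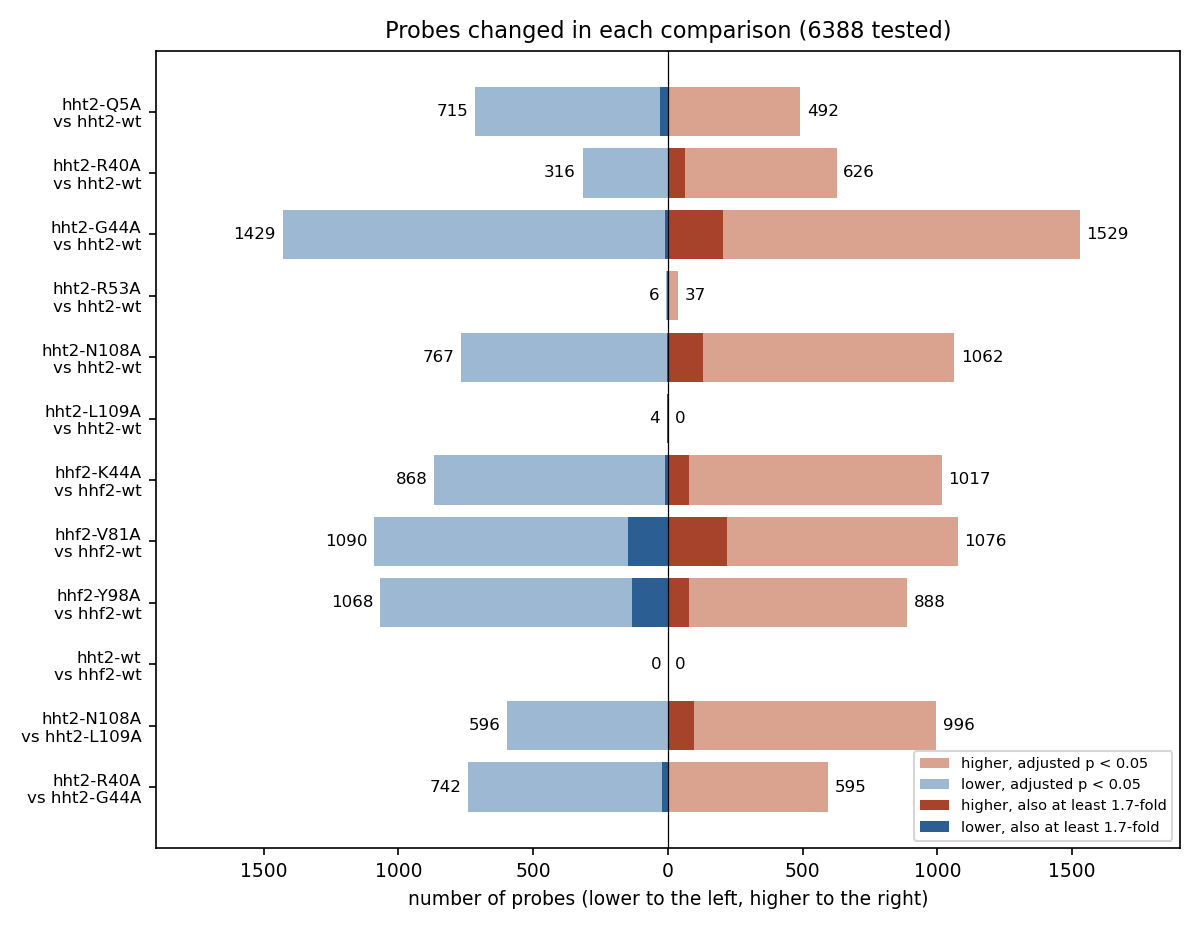
Number of probes past an adjusted p of 0.05 (limma) in each of the 12 comparisons, higher to the right and lower to the left, with the part of at least 1.7-fold in dark colour. G44A has 1529 higher and 1429 lower probes, L109A has 4 lower probes, and hht2-wt against hhf2-wt has 0.

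The H3 Q5A comparison asked which genes respond to loss of a glutamine near the H3 N terminus. The targeted gene HHT2 was lower (-0.43 ± 0.14, adjusted p = 0.0449), as were HHF2 (-0.37), HHT1 (-0.37) and HHF1 (-0.35), but these 4 calls were lost when any 1 of the 4 cultures was left out. Cross-hybridisation between the probes of HHT1 and HHT2, or of HHF1 and HHF2, was not tested in any mutant. ARG1 and ARG3 of arginine synthesis (0.87 ± 0.17, 0.00233, and 0.81 ± 0.11, 0.00024), HIS4 of histidine synthesis (0.71 ± 0.08) and GDH1, a glutamate dehydrogenase (0.78 ± 0.06, 1.53e-06), rose. CHA1, the serine and threonine deaminase (-1.33 ± 0.12, 6.81e-06), CWP1, a cell wall mannoprotein (-1.25 ± 0.13, 2.6e-05), and CUP1-2, a metallothionein (-1.39, 1.48e-05), fell. Altogether 492 genes were higher and 715 lower, of which 6 and 30 by at least 1.7-fold. The total of 1207 was 548 without Q5A a, 737 without Q5A b and 626 without hht2-wt a.

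In Q5A, 34 of 48 Gcn4 amino-acid targets were higher and 3 lower (36 and 3 adjusted over the list alone). Camera gave an adjusted p = 1.66e-15, and adjusted p = 0.248 with an estimated correlation. Methionine and sulphur genes, such as MET14 (0.58), had 14 of 25 higher (16 adjusted over the list alone), with a camera adjusted p = 7e-07, and adjusted p = 0.248 with an estimated correlation. Chromatin regulators were called upward with 6 of 35 higher and 1 lower (8 and 2 adjusted over the list alone), at 0.0313, and adjusted p = 0.444 with an estimated correlation. Called downward were the histone genes (8 of 11 lower) and the promoter-nucleosome-regulated genes (10 of 19 lower, 2 higher), with the same counts when adjusted over the list alone. Their camera adjusted p was 0.00699 and 0.00607, and adjusted p = 0.472 and 0.248 with an estimated correlation. Ergosterol genes (6 of 24 lower), stress-induced genes (8 of 51) and construction markers (6 of 13) were also called downward, with 10, 8 and 6 lower when adjusted over the list alone. In that order, the camera adjusted p was 0.0251, 0.0143 and 0.0296, and adjusted p = 0.581, 0.778 and 0.581 with an estimated correlation. Of the 6 construction markers, 4 are HHT1, HHF1, HHT2 and HHF2, which the histone list also counts. Calls were lost without Q5A a or hht2-wt a (chromatin regulators), Q5A a or hht2-wt b (stress-induced genes), Q5A b or hht2-wt b (ergosterol), and Q5A b or hht2-wt a (construction markers). Those of the construction markers and promoter-nucleosome-regulated genes were also lost without chromosomes I, VIII and XIV, an alternative chosen after seeing the data.

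In H3 R40A, a substitution near the N-terminal helix of H3, the targeted gene HHT2 read 0.12 (adjusted p = 0.597). SNZ1 and SNO1 of vitamin B6 synthesis (1.36 ± 0.13, 1.44e-05, and 1.16), MAL12, a maltase (1.24 ± 0.08, 3.85e-07), MCH2, related to monocarboxylate transporters (1.21 ± 0.09, 1.22e-06), and GPH1, the glycogen phosphorylase (1.16), were higher. HXK1, a hexokinase, was also higher (1.37 ± 0.30, 0.00635), a call lost without R40A a or hht2-wt a. CDC26, a subunit of the anaphase-promoting complex (-0.72 ± 0.07, 1.24e-05), CUP1-2 (-0.69, 0.00311) and YIL014C-A (-0.62 ± 0.05, 4.35e-06) led the lower genes. There were 626 higher genes, 63 of them by at least 1.7-fold, and 316 lower genes, 0 of them by that much. The total of 942 was 424 without R40A a, 610 without hht2-wt a and 499 without hht2-wt b.

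Of 51 stress-induced genes, 32 were higher in R40A and 0 lower (42 and 0 adjusted over the list alone). Camera gave an adjusted p = 1.38e-16, and adjusted p = 0.444 with an estimated correlation. Genes within 20 kb of a chromosome end (66 of 190 higher, 4 lower) and PAU and COS genes (15 of 25 higher, 1 lower) were called upward, with 74 and 6, and 18 and 1, when adjusted over the list alone. Their camera adjusted p was 1.3e-08 and 1.55e-05, and adjusted p = 0.273 and 0.497 with an estimated correlation. Meiosis genes, such as RED1 of the meiotic chromosome axis (0.67), had 15 of 45 higher and 2 lower, and DNA damage genes, such as RNR3 of ribonucleotide reductase (0.57), had 7 of 18 higher (16 and 2, and 9, adjusted over the list alone). Camera adjusted p was 0.000105 and 0.00129, and adjusted p = 0.444 and 0.271 with an estimated correlation. The alpha-specific genes, with SAG1 (the alpha-agglutinin) at 0.75 ± 0.06, had 2 of 4 higher and the hexose transporters 4 of 16 (3 and 6 adjusted over the list alone), at 0.0137 and 0.0328, and adjusted p = 0.444 for each with an estimated correlation. Called downward were Gcn4 targets (8 of 48 lower, 3 higher) and ribosome biogenesis (2 of 58 lower), with 9 and 4, and 0, when adjusted over the list alone. By camera, adjusted p was 0.00546 and 0.000271, and adjusted p = 0.581 and 0.617 with an estimated correlation. Calls were lost without R40A b or hht2-wt b (alpha-specific genes), R40A a, G44A a, hht2-wt b or chromosomes I, VIII and XIV (hexose transporters), and R40A a (ribosome biogenesis).

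In H3 G44A, HHT2 itself read -0.03 (adjusted p = 0.89), and 2958 genes passed the adjusted p limit, the highest count of the 9 mutants, while at 1.7-fold V81A had more (370 against 218). Of those, 151 in V81A were higher genes of chromosome XIV, against 10 in G44A. RTN2, a reticulon (2.32 ± 0.20, 8.89e-07), HXK1 (2.24 ± 0.30, 3.42e-05), HSP78, a mitochondrial chaperone (2.11 ± 0.18, 5.89e-07), HSP12, a membrane-associated stress protein (1.95 ± 0.30, 0.000121), and GPH1 (1.87 ± 0.21, 9.15e-06), led the higher genes. CHA1 (-1.10 ± 0.12, 6.6e-06), YDL085C-A (-0.94 ± 0.06, 3.56e-08), YLR126C (-0.88 ± 0.08, 1.79e-06) and CDC26 (-0.87 ± 0.07, 3.48e-07) led the lower ones, which included RPA135, a subunit of RNA polymerase I (-0.57). In all 1529 genes were higher and 1429 lower, of which 206 and 12 by at least 1.7-fold. Genes of chromosomes I and VIII had a median of 0.18 and 0.19, unequal between the cultures (chromosome I 0.39 in culture a and 0.00 in b, chromosome VIII 0.07 and 0.33), and 32 of 83 and 119 of 252 genes were higher there. Without chromosomes I, VIII and XIV, an alternative chosen after seeing the data, 2632 genes changed in place of 2958.

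All 51 stress-induced genes were higher in G44A, also when adjusted over the list alone (51). Camera gave an adjusted p = 2.55e-20, and adjusted p = 0.396 with an estimated correlation. Heat-shock genes, such as KAR2 of the endoplasmic reticulum (0.84), had 17 of 21 higher (17 higher and 1 lower adjusted over the list alone), with a camera adjusted p = 3.1e-05, and adjusted p = 0.444 with an estimated correlation. Meiosis genes, such as the recombinase DMC1 (1.07), had 26 of 45 higher and 4 lower, and genes within 20 kb of an end 89 of 190 higher and 16 lower (27 and 4, and 89 and 18, adjusted over the list alone). These lists had a camera adjusted p of 2.29e-05 and 1.37e-06, and adjusted p = 0.444 and 0.32 with an estimated correlation. DNA damage genes (11 of 18 higher), cell wall integrity genes (10 of 17 higher, 1 lower), hexose transporters (9 of 16 higher, 1 lower) and the proteasome (13 of 33 higher, 1 lower) were also called upward, with 12, 12, 9 and 13 higher when adjusted over the list alone. The adjusted p from camera was 0.000675, 0.00235, 0.00546 and 0.00374, and adjusted p = 0.248, 0.444, 0.32 and 0.495 with an estimated correlation. Ribosome biogenesis, with NOP58 at -0.54, was called downward with 44 of 58 lower, as were ribosomal proteins with 45 of 127 lower and 2 higher (46, and 41 and 2, adjusted over the list alone). With camera, adjusted p was 1.14e-10 and 2.92e-05, and adjusted p = 0.444 for each with an estimated correlation. Purine and one-carbon genes, with SHM2 at -0.55, had 7 of 17 lower (7 adjusted over the list alone), at 0.0228, and adjusted p = 0.478 with an estimated correlation. The calls of the proteasome and of the purine genes were lost without G44A a, and that of the hexose transporters without chromosomes I, VIII and XIV.

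R40A and G44A, which lie close together in H3, were also tested directly. HSP12 (-1.40 ± 0.30, adjusted p = 0.00516), MSC1 (-1.22 ± 0.19, 0.000905) and CRG1, a methyltransferase (-1.19 ± 0.10, 2.82e-05), were lower in R40A than in G44A. CRG1 lies on chromosome VIII, whose genes had a median of 0.19 in G44A. YHB1, a flavohaemoglobin (0.97 ± 0.17, 0.00174), YIR043C (0.76 ± 0.18, 0.0105) and COS10 (0.76 ± 0.16, 0.00594) were higher. The calls of HSP12 and COS10 were lost without R40A b or G44A a, and that of YIR043C without R40A b or G44A b. In all 1337 genes differed, 595 higher in R40A and 742 lower, and the count was 399 without R40A b. With R40A against hht2-wt and G44A against hhf2-wt, so that no control array was shared (chosen after seeing the data), 561 genes were higher and 260 lower in both mutants (149.9 and 72.7 for independent lists), and 2 changed in opposite directions. With the controls exchanged, 571 were higher, 297 lower and 0 opposite (158.5 and 86.1 for independent lists).

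In H3 R53A the HHT2 probe itself was far lower (-1.39 ± 0.14, adjusted p = 0.00026). TIP1, a cell wall mannoprotein (0.81 ± 0.07, 5.8e-05), SOR2, a sorbitol dehydrogenase (0.65 ± 0.09, 0.00247), FSP2, an isomaltase (0.58 ± 0.09, 0.00306), and RNR4 and RNR2 of ribonucleotide reductase (0.39 and 0.33) were higher, and CUP1-2 was lower (-0.85, 0.00599). Altogether 37 genes were higher and 6 lower. The total of 43 was 10 without R53A a, 20 without R53A b and 19 without hht2-wt b, but 552 with only the 4 arrays compared, 137 against both controls, 68 with the authors' value table and 81 against hhf2-wt (the last chosen after seeing the data). Without R53A a each gene named here except HHT2 and TIP1 lost its call.

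Lists in R53A were called with few changed members. Genes within 20 kb of an end had 6 of 190 higher, meiosis genes 1 of 45 and DNA damage genes 2 of 18 (21 higher and 1 lower, 2 higher and 2 higher adjusted over the list alone). Tested with camera, they had an adjusted p of 7.19e-07, 4.06e-06 and 0.00667, and adjusted p = 0.32, 0.382 and 0.32 with an estimated correlation. The zinc regulon (median 0.16) and PAU and COS genes (0.21) were called upward with 0 of 10 and 0 of 25 changed (5 higher and 1 lower, and 3 higher and 1 lower, adjusted over the list alone). Each had a camera adjusted p = 0.000399, and adjusted p = 0.248 and 0.581 with an estimated correlation. Called downward were the histone genes (median -0.16) and the construction markers, both with HHT2 as the lower gene, 1 of 11 and 1 of 13 (1 lower, and 1 lower and 1 higher, adjusted over the list alone). Camera adjusted p was 1.39e-07 and 0.00349, and adjusted p = 0.248 and 0.489 with an estimated correlation. Oxidative phosphorylation (median -0.10), Gcn4 targets (-0.09), G1/S genes (-0.04) and the iron regulon (-0.10) were called downward with 0 changed members each (0 lower, 2 lower, 0 lower and 1 higher adjusted over the list alone). By camera, adjusted p was 1.33e-06, 8.34e-06, 0.00754 and 0.0495, and adjusted p = 0.54, 0.444, 0.444 and 0.581 with an estimated correlation. Calls were lost without hht2-wt a (DNA damage, PAU and COS, construction markers), chromosomes I, VIII and XIV (construction markers), hht2-wt b (G1/S), and R53A b, hht2-wt a, hht2-wt b or any of 8 cultures of other strains (iron).

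In H3 N108A the targeted gene HHT2 read 0.00 (adjusted p = 0.992), while HHF2, which encodes H4, was higher (0.55 ± 0.10, 0.00114). SNZ1 (1.66 ± 0.13, 1.91e-06), RTN2 (1.62 ± 0.20, 6.68e-05), SER3 of serine synthesis (1.44 ± 0.13, 6.06e-06), GND2 of the pentose phosphate pathway (1.42 ± 0.11, 1.42e-06) and THI11 of thiamine synthesis (1.41) led the higher genes. ARG3 (-0.78 ± 0.11, 0.000219), SAM3, a permease of S-adenosylmethionine (-0.65 ± 0.11, 0.000521), and SPT4, a transcription elongation factor (-0.64 ± 0.07, 2.55e-05), led the lower ones. Of 1829 changed genes, 1062 were higher and 767 lower (130 and 3 by at least 1.7-fold), and without hht2-wt a the count was 925.

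In N108A, 41 of 51 stress-induced genes and 13 of 21 heat-shock genes were higher, such as SSA1, a chaperone gene (0.62), and BTN2 (0.94), with 47 and 15 when adjusted over the list alone. These lists had a camera adjusted p of 1.15e-14 and 3.36e-05, and adjusted p = 0.444 for each with an estimated correlation. DNA damage genes had 11 of 18 higher and the proteasome 8 of 33 (11 and 8 adjusted over the list alone). The adjusted p from camera was 1.97e-05 and 0.00546, and adjusted p = 0.248 and 0.495 with an estimated correlation. HUG1, induced by DNA damage, read 1.09, a call lost without N108A b or hht2-wt a. Sum1-repressed genes, with BNA2 of NAD synthesis at 1.08, had 9 of 14 higher, and meiosis genes 19 of 45 (10 higher and 1 lower, and 20 higher, adjusted over the list alone). With camera, adjusted p was 0.000719 and 0.000264, and adjusted p = 0.313 and 0.444 with an estimated correlation. PAU and COS genes, with COS12 at 1.27, had 10 of 25 higher and 1 lower, and genes within 20 kb of an end 76 of 190 higher and 12 lower (13 and 1, and 81 and 17, adjusted over the list alone). Tested with camera, they had an adjusted p of 0.000467 and 2.35e-07, and adjusted p = 0.581 and 0.32 with an estimated correlation. Called downward were ribosome biogenesis, with NOP4 at -0.38 and 24 of 58 lower, and ribosomal proteins, with RPL16A at -0.42 and 23 of 127 lower and 5 higher (29, and 22 and 5, adjusted over the list alone). Camera adjusted p was 8.88e-10 and 0.000472, and adjusted p = 0.469 and 0.472 with an estimated correlation. The call of the proteasome was lost without N108A a.

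H3 L109A, the neighbouring substitution, left HHT2 at 0.33 (adjusted p = 0.995) and changed 4 probes, all lower. These were CUP1-2 (-1.46 ± 0.13, 9.92e-05), YHR054C, a gene of the same repeat (-0.97 ± 0.10, 0.000131), and the unnamed probes SCAB002687 (-1.37 ± 0.14, 0.000131) and SCAB002688 (-1.04 ± 0.09, 4.65e-05). Without L109A a, 8 genes changed. Stress-induced genes (median 0.14) and histone genes (0.11) were called upward with 0 of 51 and 0 of 11 changed, also 0 and 0 when adjusted over the list alone. By camera, adjusted p was 4.37e-10 and 0.00349, and adjusted p = 0.495 and 0.444 with an estimated correlation. Gcn4 targets (median -0.09), heat-shock genes (-0.06) and promoter-nucleosome-regulated genes (-0.04) were called downward with 0 of 48, 0 of 21 and 1 of 19 lower (0, 0 and 2 adjusted over the list alone). These lists had a camera adjusted p of 1.07e-08, 0.00137 and 0.0273, and adjusted p = 0.372, 0.497 and 0.285 with an estimated correlation. The 1 lower member of the last list is CUP1-2, and the list mean was -0.11. Calls were lost without L109A b or hht2-wt a (histone genes) and without L109A a, hht2-wt a, hht2-wt b or chromosomes I, VIII and XIV (promoter-nucleosome-regulated genes).

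Tested directly, N108A and L109A differed in 1592 genes, 996 higher in N108A and 596 lower. SNZ1 (1.90 ± 0.13, adjusted p = 6.65e-07) and 2 unnamed probes led the higher genes. ARG3 (-0.71 ± 0.11, 0.000576), YCP4, a flavodoxin-like protein (-0.67 ± 0.07, 1.43e-05), and SAM3 (-0.64 ± 0.11, 0.000715) led the lower ones. The count was 579 without L109A a, 878 without L109A b and 989 without N108A a. The sample titles of N108A and L109A also differ in a number (2 and 1) whose meaning the labels do not give.

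In H4 K44A the targeted gene HHF2 read 0.24 (adjusted p = 0.0904) and HHT2 0.16. Both lie on chromosome XIV and read below the median of its genes, 0.39. TIP1 (1.57 ± 0.07, 4e-09), SER3 (1.36 ± 0.13, 5.9e-06), THI11 (1.35 ± 0.06, 4e-09), MAL12 (1.20) and MCH2 (1.20) led the higher genes. HSP12 (-1.33 ± 0.30, 0.00393), GTR2, a GTPase of the TORC1 pathway (-0.89 ± 0.04, 4e-09), HNM1, the choline transporter (-0.88 ± 0.10, 1.33e-05), and ARG3 (-0.87 ± 0.11, 5.8e-05) were among the lowest. HTB1 (-0.82 ± 0.07), HTB2 (-0.74 ± 0.08) and HTA2 (-0.61 ± 0.05) fell, and HTA1 did too (-0.75 ± 0.05), but not with print-tip loess (-0.32, adjusted p = 0.154). There were 1885 changed genes, 1017 higher and 868 lower, and the count was 1140 without K44A b and 1255 without hhf2-wt a. Genes of chromosome XIV were higher as a block: their median was 0.39 over 358 genes (0.39 in culture a, 0.38 in b), 95.3% were above 0, and they made up 285 of the 1017 higher genes. Without chromosomes I, VIII and XIV, chosen after seeing the data, 1489 genes changed, of which 45.9% were higher against 54% with all genes.

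Heat-shock genes, such as BTN2 (0.88) and, on chromosome XIV with its median of 0.39, the chaperone genes SIS1 (1.02) and HCH1 (0.89), were called upward in K44A with 18 of 21 higher (18 adjusted over the list alone). Camera gave an adjusted p = 2.38e-09, and adjusted p = 0.32 with an estimated correlation. Genes within 20 kb of an end had 75 of 190 higher and 7 lower, and PAU and COS genes 10 of 25 higher (79 and 7, and 11, adjusted over the list alone). The adjusted p from camera was 2.69e-09 and 0.000363, and adjusted p = 0.253 and 0.581 with an estimated correlation. Meiosis genes, such as DMC1 (0.91) and the regulator IME1 (0.55), had 16 of 45 higher and 2 lower, DNA damage genes 5 of 18 higher and 1 lower, and the proteasome 5 of 33 higher and 1 lower (16 and 3, 7 and 1, and 5 and 0, adjusted over the list alone). With camera, adjusted p was 0.00543, 0.0123 and 0.00713, and adjusted p = 0.497, 0.374 and 0.497 with an estimated correlation. Called downward were histone genes (6 of 11 lower), ribosomal proteins (30 of 127 lower, 3 higher) and ribosome biogenesis (17 of 58 lower, 5 higher), with 7 and 1, 29 and 3, and 21 and 5 when adjusted over the list alone. Tested with camera, they had an adjusted p of 0.00601, 0.00218 and 0.00248, and adjusted p = 0.472, 0.497 and 0.666 with an estimated correlation. Purine and one-carbon genes, with GCV2 of glycine cleavage at -0.75, had 8 of 17 lower and 1 higher, oxidative phosphorylation 6 of 36 lower, and chromatin regulators 11 of 35 lower and 2 higher (8 and 1, 2, and 11 and 3, adjusted over the list alone). Camera adjusted p was 0.00978, 0.02 and 0.049, and adjusted p = 0.444, 0.75 and 0.472 with an estimated correlation. Calls were lost without hhf2-wt a (meiosis), K44A a (oxidative phosphorylation), and K44A b, hhf2-wt a, any of 8 cultures of other strains, or chromosomes I, VIII and XIV (chromatin regulators).

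**Figure D2:**
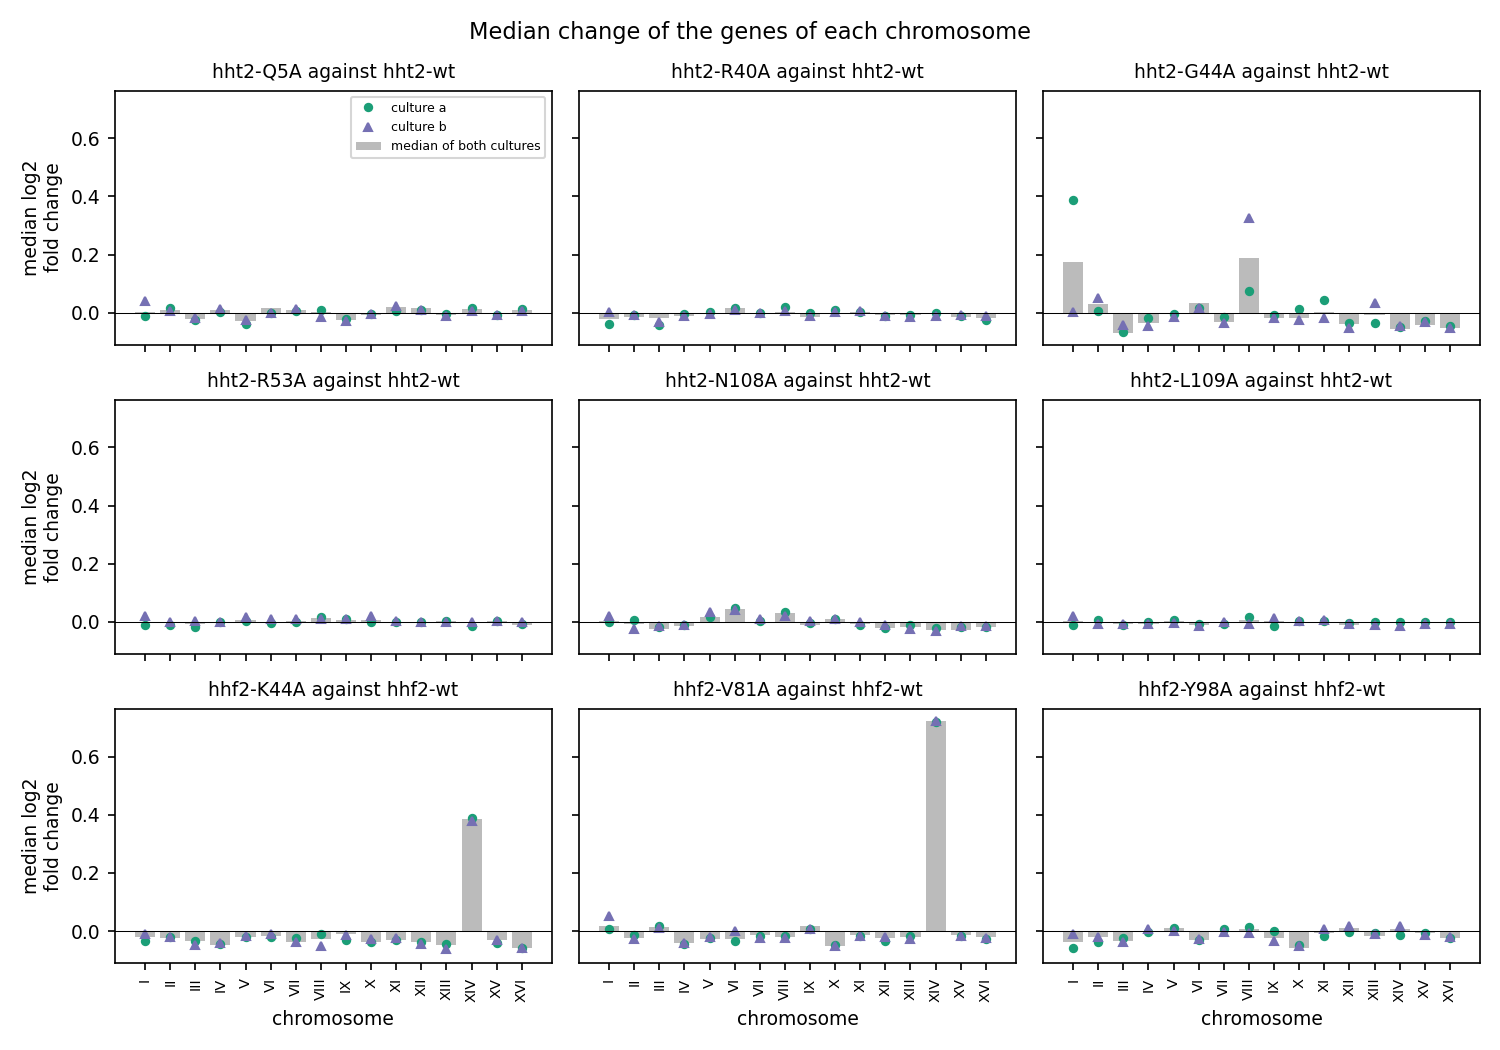
Median log2 fold change of the genes of each of 16 chromosomes in each of the 9 mutants (bars, both cultures; points, culture a and culture b). Chromosome XIV stands at 0.72 in V81A and 0.39 in K44A, and chromosomes I and VIII at 0.18 and 0.19 in G44A.

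In H4 V81A the targeted gene HHF2 was higher (0.88 ± 0.10, adjusted p = 7.2e-06), as were HHT2 (0.87 ± 0.14), HHF1 (0.67) and HHT1 (0.54), while HTA2 (-0.65), HTB1 (-0.58) and HTB2 (-0.53) were lower. Whether the HHF1 and HHT1 probes also took up signal of HHF2 and HHT2 was not tested. HHF2, HHT2 and, among genes named further on, YGP1 and MFA2 lie on chromosome XIV, whose 358 genes had a median of 0.72 (0.72 in each culture) with 96.4% above 0. HTA1 was lower too (-0.62), but not past the threshold with print-tip loess (-0.09, adjusted p = 0.718). HXT2, a glucose transporter (2.17 ± 0.10, 3.95e-09), SNZ1 (1.88 ± 0.13, 7.14e-08), SNO1 (1.83 ± 0.12, 3.16e-08) and GSC2, a glucan synthase subunit (1.79 ± 0.15, 3.08e-07), led the higher genes. YGP1, a secreted glycoprotein (-2.33 ± 0.18, 1.21e-07), YRO2 (-2.13 ± 0.14, 3.04e-08) and MRH1 (-1.67 ± 0.11, 3.48e-08), both membrane proteins, and FAR1, which arrests the cell cycle in response to pheromone (-1.74 ± 0.15), were lower. There were 2166 changed genes, 1076 higher and 1090 lower (221 and 149 by at least 1.7-fold), and 1405 without V81A a. Chromosome XIV held 321 of the 1076 and 151 of the 221. Without chromosomes I, VIII and XIV 1732 genes changed and 41.2% were higher, against 49.7% with all genes.

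Among mating genes of a cells, AGA2, the a-agglutinin (-1.58 ± 0.19), ASG7 (-1.52 ± 0.24), BAR1, the alpha-factor protease (-1.41 ± 0.16), STE2, the alpha-factor receptor (-1.11), and STE6, the a-factor exporter (-1.11), were lower in V81A. MFA2 read -0.25 (adjusted p = 0.0584). Of the 7 a-specific genes 6 were lower, and of the 18 haploid and mating pathway genes 16 (7 and 17 adjusted over the list alone). By camera, adjusted p was 9.5e-05 and 1.17e-10, and adjusted p = 0.444 and 0.32 with an estimated correlation. IME4, normally low in haploid cells, was higher (1.20 ± 0.15), as was MATALPHA2 (0.55 ± 0.08), while HIS3, a histidine marker (-1.24 ± 0.14, 7.56e-06), and HO (-1.19 ± 0.18, 9.32e-05) were lower.

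Gcn4 targets, with LEU4 of leucine synthesis at 1.52 (on chromosome XIV, whose median was 0.72), were called upward in V81A with 38 of 48 higher (41 higher and 1 lower adjusted over the list alone). Camera gave an adjusted p = 2.65e-17, and adjusted p = 0.248 with an estimated correlation. PAU and COS genes had 9 of 25 higher, genes within 20 kb of an end 63 of 190 with 14 lower, and the iron regulon, with the cell wall mannoprotein FIT3 at 1.34, 9 of 22 with 2 lower (11, 67 and 18, and 10 and 2, adjusted over the list alone). These lists had a camera adjusted p of 3.97e-05, 8.81e-05 and 0.04, and adjusted p = 0.534, 0.444 and 0.576 with an estimated correlation. Called downward were G2/M genes, such as the mitotic exit kinase DBF2 (-0.55), with 10 of 16 lower, and oxidative phosphorylation with 21 of 36 lower and 1 higher (13, and 22 and 1, adjusted over the list alone). The adjusted p from camera was 9.12e-05 and 5.68e-05, and adjusted p = 0.248 and 0.6 with an estimated correlation. Stress-induced genes had 20 of 51 lower and 5 higher, cell wall integrity genes, such as CHS3 of chitin synthesis (-0.45), 8 of 17 lower, and promoter-nucleosome-regulated genes 10 of 19 lower and 2 higher (27 and 5, 11, and 11 and 2, adjusted over the list alone). With camera, adjusted p was 0.000215, 0.00216 and 0.0127, and adjusted p = 0.661, 0.444 and 0.248 with an estimated correlation. The 10 lower members of the last list include BAR1 and STE6, counted above as a-specific, and HO. The call of the iron regulon was lost without V81A a, hhf2-wt b or chromosomes I, VIII and XIV, and that of the promoter-nucleosome-regulated genes without those chromosomes.

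H4 Y98A left the targeted gene HHF2 at -0.15 (adjusted p = 0.295). MFA2 and MFA1, which encode a-factor (-4.23 ± 0.10, 1.02e-12, and -3.91 ± 0.12, 1.34e-11), STE2 (-4.23 ± 0.11, 3.28e-12), STE18, the G-protein gamma subunit (-3.40 ± 0.15, 1.18e-09), and HO, the mating-type switching endonuclease (-3.18 ± 0.18, 9.95e-09), were lower, as was HIS3 (-3.55 ± 0.14, 4.97e-10). All 7 a-specific genes were lower, with a median of -3.49, and so were 15 of 18 haploid and mating pathway genes (7 and 15 adjusted over the list alone). Tested with camera, they had an adjusted p of 1.8e-12 and 8e-17, and adjusted p = 0.248 for each with an estimated correlation. RME1, a repressor of meiosis, was lower (-1.36 ± 0.17), and IME4 (1.95 ± 0.15, 2.24e-07) and MATALPHA2 (0.83 ± 0.08, 1.89e-06) were higher, while MATALPHA1 read 0.19 (0.262) and HMRA1 -0.10 (0.769). Other higher genes were SNO1 (2.31 ± 0.12, 3.93e-09), HUG1 (2.24 ± 0.30, 5.94e-05), HPF1, a cell wall glycoprotein (2.23 ± 0.15, 5.68e-08), and SNZ1 (2.02 ± 0.13, 6.2e-08). In all 1956 genes changed, 888 higher and 1068 lower (80 and 134 by at least 1.7-fold), and 1252 without hhf2-wt a.

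**Figure D3:**
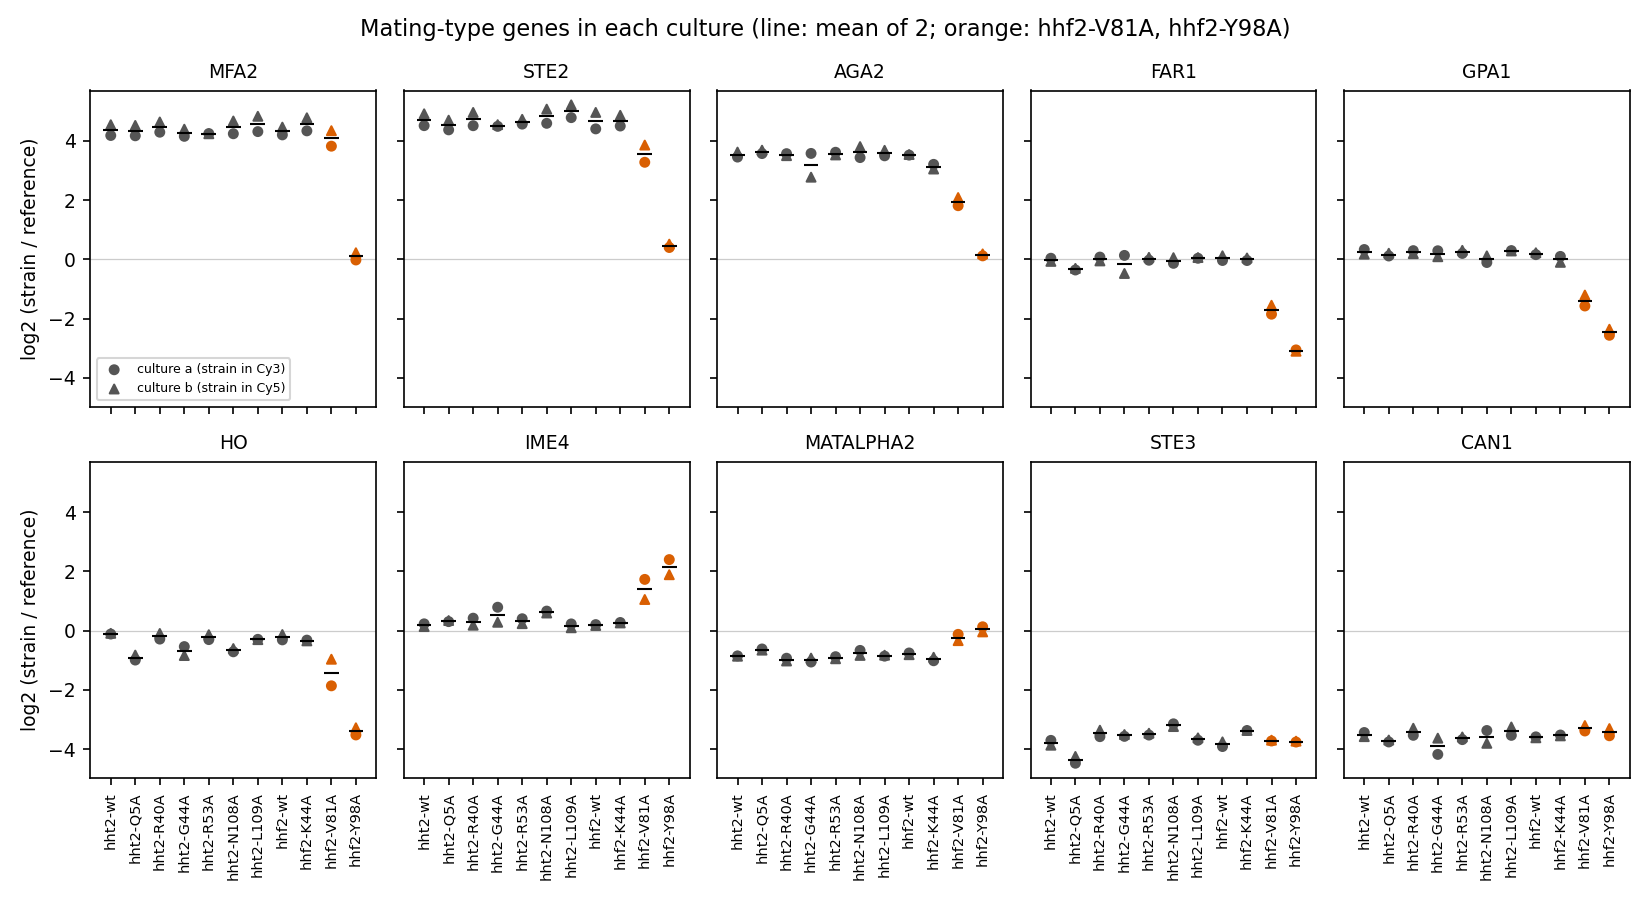
Log2 of strain over reference signal for 10 mating genes and markers in each of the 2 cultures of the 11 strains (points; line, mean of 2), with V81A and Y98A in orange. The a-specific genes MFA2, STE2 and AGA2 are lowest in Y98A.

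Among the other lists in Y98A, meiosis genes, such as the recombination gene SAE3 (1.78), had 19 of 45 higher and 3 lower, and Sum1-repressed genes 7 of 14 higher and 2 lower, with the same counts when adjusted over the list alone. Camera adjusted p was 4.06e-06 and 0.0127, and adjusted p = 0.382 and 0.444 with an estimated correlation. Gcn4 targets, with LYS1 of lysine synthesis at 1.13, had 23 of 48 higher and 3 lower (28 and 4 adjusted over the list alone), with a camera adjusted p = 8.34e-06, and adjusted p = 0.444 with an estimated correlation. Stress-induced genes (18 of 51 higher), heat-shock genes, such as AHA1 (0.47; 8 of 21), and the proteasome (7 of 33) were called upward, with 18, 10 and 7 higher when adjusted over the list alone. By camera, adjusted p was 2.82e-05, 0.000675 and 0.00373, and adjusted p = 0.617, 0.495 and 0.495 with an estimated correlation. PAU and COS genes, with COS12 at 1.43, had 8 of 25 higher, and the iron regulon, with SIT1, a siderophore transporter, at 0.70, had 8 of 22 higher and 1 lower, with the same counts when adjusted over the list alone. These lists had a camera adjusted p of 0.00013 and 0.0371, and adjusted p = 0.562 and 0.571 with an estimated correlation. Promoter-nucleosome-regulated genes were called downward with 9 of 19 lower and 2 higher (9 and 2 adjusted over the list alone), at 0.0375, and adjusted p = 0.32 with an estimated correlation. Its lower members include BAR1 (-3.49) and STE6 (-2.78), also counted as a-specific, and HO (-3.18), and the list had a mean of -0.52 but a median of -0.13. The call was lost without Y98A a, hhf2-wt b or chromosomes I, VIII and XIV, and that of the iron regulon without Y98A b, hhf2-wt b or those chromosomes.

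**Figure D4:**
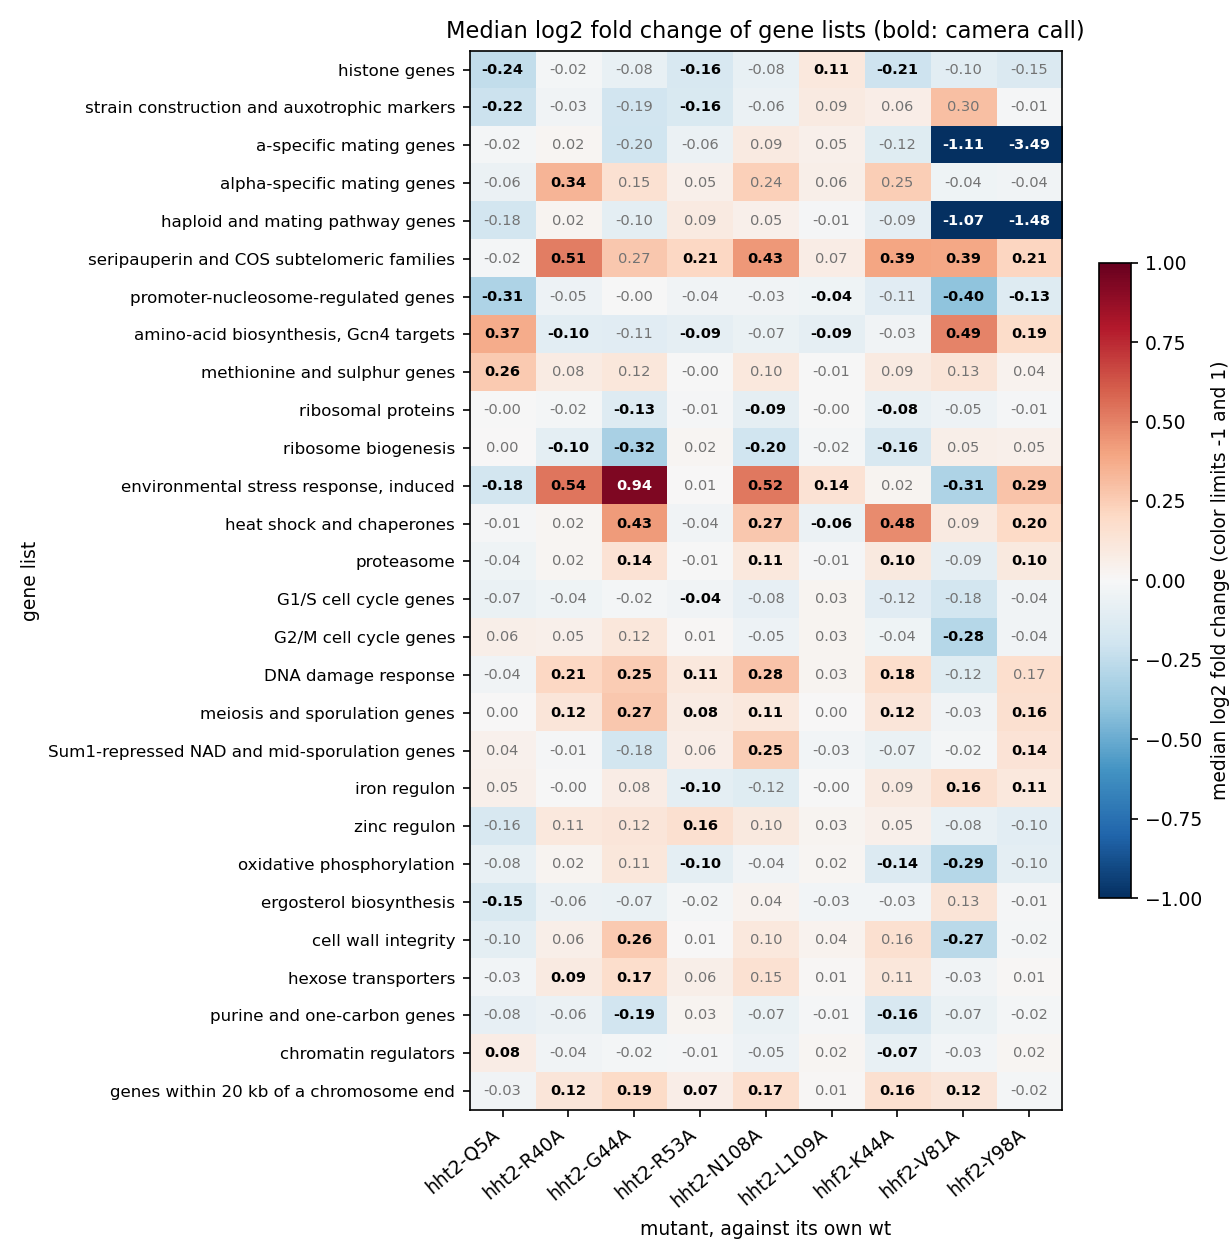
Median log2 fold change of the 28 gene lists called in at least 1 mutant, for each of the 9 mutants, coloured from -1 to 1, with camera calls in bold. Stress-induced genes are at 0.94 in G44A and -0.31 in V81A, and a-specific genes at -3.49 in Y98A.

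Of the histone and construction genes not given so far, HTB1 (-0.26), HTB2 (-0.24), HTA1 (-0.19), HTA2 (-0.17) and ADE2 (-0.15) were lower in Q5A, calls lost without Q5A a or Q5A b, as was HO (-0.81 ± 0.18, adjusted p = 0.00575), a call lost without hht2-wt a. In R40A HTB1 was lower (-0.22, lost without R40A a, R40A b or hht2-wt b). In G44A HO (-0.59), MET17 (-0.48), HIS3 (-0.40) and LYS2 (-0.19) were lower, each lost without hht2-wt a. In N108A HO (-0.56) and HTB2 (-0.23) were lower and ADE2 (0.16) higher, each lost without N108A a or hht2-wt b. In K44A HTZ1 (-0.27), CSE4 (-0.18) and ADE2 (-0.13) were lower, each lost without K44A b, and in V81A ADE2 (-0.25) and CSE4 (-0.22) were, the latter lost without V81A b or hhf2-wt b. In Y98A HTB2 (-0.28), HTB1 (-0.24), HTA1 (-0.24) and HTA2 (-0.20) were lower, each lost without Y98A a or hhf2-wt a and with median centring, and HTA1 read 0.10 with print-tip loess. Leaving out another single culture ended some of these calls as well.

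Some genes were called in most mutants. SNZ1, SNO1, TIP1, MAL12, UGA4, a permease of aminobutyrate, and DDI2 and DDI3, cyanamide hydratases, were higher in 7 of the 9 mutants, and CUP1-2 was lower in 7. UGA4 was also lower in 1, Q5A (-0.34, a call lost without Q5A a or hht2-wt a). In all 18 genes were higher and 5 lower in 7 mutants, and 0 in 8 or 9. Mutants of the same histone share their controls, so these calls are not independent. DDI2 and DDI3 are near-identical copies, and cross-hybridisation of their probes was not tested. Lists called in no mutant were the phosphate regulon (16 genes, lowest camera adjusted p = 0.055, in N108A), galactose genes (7 genes, 0.181, K44A), glycolysis (16 genes, 0.178, K44A) and M/G1 genes (18 genes, 0.125, Q5A). Camera made 88 calls, 51 upward and 37 downward.

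Whether H3 and H4 mutants move the same genes was asked over 18 pairs that share no control. The median correlation across genes was 0.104 (-0.203 to 0.61), 0.0476 without hht2-wt b and 0.0428 with median centring, and 0.0126 and 0.0686 with profiles of culture a or b alone. The profile of K44A correlated with those of R40A (0.61), G44A (0.60), N108A (0.55) and R53A (0.47), and by 0.236 with L109A and -0.0354 with Q5A. K44A, R40A, G44A, N108A and Q5A carry 2 in their sample titles, and R53A and L109A carry 1. V81A carries 2 as well, and its r was -0.069 with R40A, -0.055 with G44A, -0.203 with N108A and 0.115 with Q5A. Among pairs that share a control, R40A and G44A had an r of 0.82 and a covariance of 0.0514, and V81A and Y98A 0.44 and 0.0498, against 0.504 and 0.00357 for simulated unchanged strains. With a different control for each mutant of the pair, chosen after seeing the data, R40A and G44A had an r of 0.81 and 0.77 in the 2 orders (covariance 0.0512 and 0.0505), and V81A and Y98A 0.43 in each (0.0482).

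**Figure D5:**
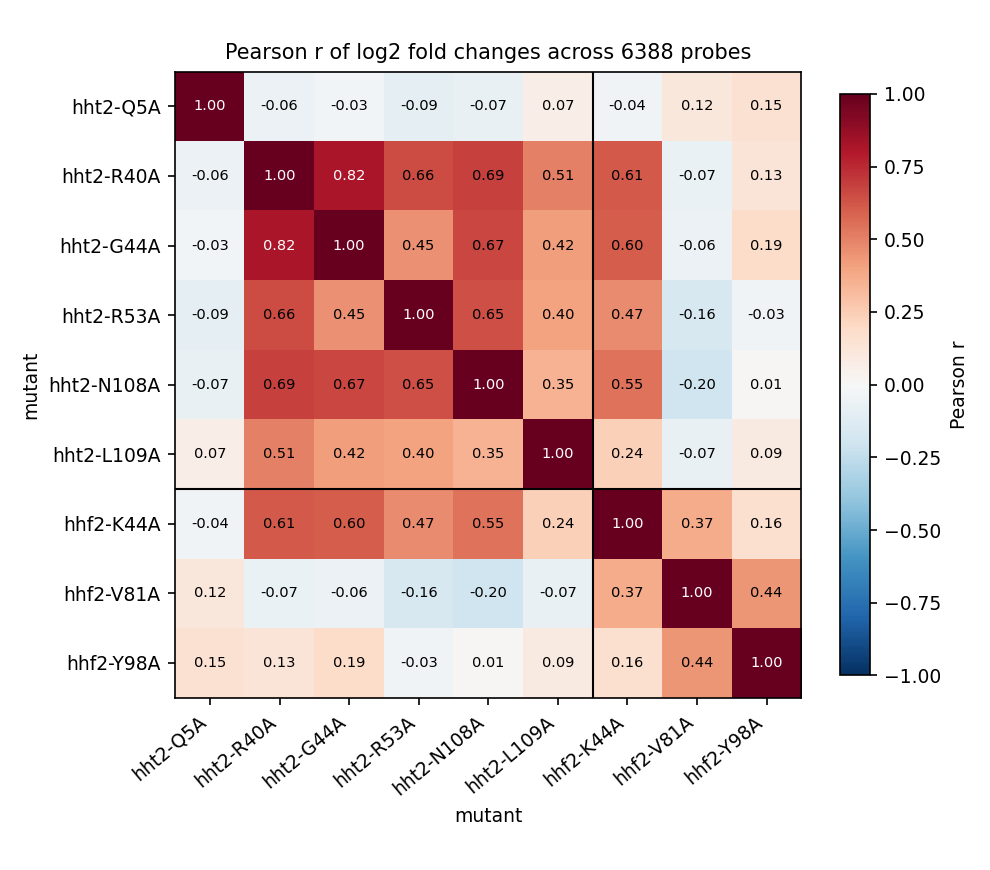
Pearson r across 6388 probes between the log2 fold changes of the 9 mutants. R40A and G44A have an r of 0.82, and pairs of an H3 and an H4 mutant run from -0.203 to 0.61.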

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

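Of the tests in this part, those of reference-strain cells, of alpha2, of a cell mixture and of the CUP1 repeat were chosen only after the result was seen. Neighbouring H3 substitutions differed in a direct test: N108A and L109A in 1592 genes (579 without L109A a, 878 without L109A b, 989 without N108A a), a contrast in which the title number of the samples also differs (2 and 1), and R40A and G44A in 1337 genes (399 without R40A b).

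Genes of chromosome XIV were higher as a block in H4 V81A and K44A. For V81A, spot position is argued against, since its chromosome XIV median was 0.707 with print-tip loess. Low values in the hhf2-wt arrays are argued against for V81A too, since that median was 0.742 against hht2-wt. K44A was not put to either test. Extra copies of the chromosome may be the source. All 8 consecutive segments lay above the highest median of the 13 other chromosomes, with the lowest at 0.655 in V81A and 0.297 in K44A. With 96.4% (V81A) and 95.3% (K44A) of its genes above 0, a segment could hardly have failed this test. It therefore does not tell extra copies from another cause of a rise along the whole chromosome. DNA was not measured, so copy number itself stays open, as does a direct effect of the substitutions.

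The a-specific and haploid genes fell in H4 Y98A and, by less, in V81A. Cells of the reference strain in the Y98A cultures are argued against, since CAN1, MET17 and TRP1, high in the reference, had a median change of 0.174. Alpha2 made in cells that carry the a genes is a candidate explanation. The MATALPHA2 probe changed by 0.83 in Y98A and was past the threshold upward only in Y98A and V81A of the 9 mutants. As group medians of log2 strain over reference, however, this probe read -0.85 while MATALPHA1 read -2.99. Relative to the reference the MATALPHA2 probe thus kept more signal in the strains, and its rise cannot be assigned to alpha2 alone. A mixture with 1 share of converted cells in V81A was tested first on 8 haploid genes below -2 in Y98A. There the SD of the share was 1.44 times its mean SE, under the bound of 2. With that outcome seen, all 22 lower a-specific and haploid genes were used, where it was 2.53 times, over the bound. The SE held the error of V81A only. Of the 22 genes MFA2 gave the lowest share, 16.8%, and MFA1 the next, 39.0%. MFA2 lies on chromosome XIV, whose genes had a median of 0.72 in V81A, and the test was not repeated without it. The answer depends on the gene set, so the test does not decide on a mixture. A mixture with further changes of single genes therefore stays open, as do a diploid or a loss of silencing, which were not told apart.

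CUP1-2 and YHR054C fell in L109A, in which 4 probes changed (8 without L109A a). For less activation by the copper-responsive factor Cup2, its other targets SOD1 (0.03 ± 0.08) and CRS5 (0.15 ± 0.05) did not fall, with a median change of 0.0919. Only these 2 genes were used, and how strongly they respond to Cup2 was not measured. The test therefore does not decide on Cup2. Fewer copies of the CUP1 repeat is a candidate explanation: of the neighbours CIC1 and CPR2, the lower value was -0.00952. Copy number was not measured, and a biological explanation by the substitution itself was not tested.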

How the results depend on the processing

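Leaving out chromosomes I, VIII and XIV, and hhf2-wt as the control of the H3 mutants, were chosen after seeing the data. So were leaving out each culture for the median correlation, and a different control for each mutant of a pair. The other alternatives were chosen beforehand, and the cause was not tested except where fewer genes or arrays give it. With median centring the counts were 715 in Q5A, 484 in R40A, 19 in R53A and 669 for R40A against G44A, and the median correlation of H3 and H4 mutants 0.0428. Without the dye term they were 676 (Q5A), 529 (R40A), 19 (R53A), 1120 (N108A), 1210 (K44A), 904 (N108A against L109A) and 656 (R40A against G44A), and with only the 4 arrays compared 501 (Q5A), 552 (R53A), 8 (L109A), 918 and 378. Requiring at least 1.7-fold left 36 in Q5A, 63 in R40A, 218 in G44A, 4 in R53A, 133 in N108A, 91 in K44A, 370 in V81A, 214 in Y98A, 98 for N108A against L109A and 22 for R40A against G44A. R40A had 590 without the dimmest 25% of probes, and R53A 137 against both controls, 68 with the authors' value table and 81 against hhf2-wt. L109A had 8 with the value table, 7 against hhf2-wt and 2 without the 3 chromosomes.

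Leaving out 1 culture gave 548 to 832 in Q5A, 424 to 704 in R40A, 2179 to 2766 in G44A, 10 to 29 in R53A, 925 to 1428 in N108A, 4 to 8 in L109A, 1140 to 1402 in K44A, 1405 to 1760 in V81A, 1252 to 1554 in Y98A, 579 to 1132 for N108A against L109A, 399 to 1280 for R40A against G44A, 84 to 96 list calls, and a median correlation of 0.0476 to 0.133. The lone culture is then assumed to vary like the other strains.

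Of 364 named gene and comparison pairs past the threshold, 318 (median centring) to 358 (no background correction) of 364 kept their call under the alternatives chosen beforehand that test all of them, apart from the fold limit (183), and 1197 of 1456 did over all left-out cultures. The direction turned in 1: HTA1 in Y98A, -0.24, read 0.10 with print-tip loess. Of the pairs past no threshold, 159 values changed sign. Of 88 list calls 77 (median centring) to 88 (trended and robust prior) were kept with other processing of the arrays or model, 75 of 82 without the dimmest 25%, 77 without the 3 chromosomes, 72 with fry, and 0 with an estimated correlation. An array batch was not run, since no scan date or slide was in the files used. Probes near background (50 to 476 per channel and array) limit what could be seen of dim genes.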

Other observations

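All values in this part were chosen after the data were seen. The strains differed from the common reference in markers of strain and mating type, although the labels give BY4742 for both. As group medians of log2 strain over reference, URA3 read 4.04, HIS3 1.29, MET17 -4.63, CAN1 -3.54 and TRP1 -3.14, and HMRA1 read 4.34. Where 1 of the 2 signals was this low before background correction (MET17 70.4 to 156 in the strains, HMRA1 60.2 to 96 in the reference), the size of the ratio depends on the offset of 50 added to both. The a-specific genes had a median of 3.18 to 3.63 in the strains other than V81A (1.95) and Y98A (0.16), and the alpha-specific genes -4.69 to -4.05. The H3 and H4 genes read lower in the strains, with HHT2 at -2.12, HHT1 at -1.20, HHF2 at -0.77 and HHF1 at -0.70, while HTA2 (0.68), HTA1 (0.58), HTB1 (0.52), HTB2 (0.42) and CSE4 (0.35) read higher and LYS2 read -0.08. The reference itself cancels in each comparison of 2 strains.

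CUP1-2 was lower in 7 mutants, with -1.39 in Q5A, -1.25 in Y98A, -1.03 in V81A and -0.85 in R53A, and read -0.03 in G44A (limma adjusted p = 0.883). Relative to 4 external controls, the median of all genes read -0.08 in culture a and -1.11 in culture b of Y98A, and -0.34 and -0.56 in V81A. In hhf2-wt it read -0.04 and -0.09, and in hht2-wt -0.13 and -0.18. The cultures of other strains also differed, with 0.29 and -0.26 in L109A, 0.11 and -0.35 in G44A, and -0.20 and 0.11 in Q5A. All changes therefore hold relative to the bulk of genes only. The authors' table, with hhf2-wt as the control of all 9 mutants, has 237 (L109A) to 3421 (G44A) of 6182 probes at a corrected limma p-value below 0.05. Of the same probes 2 (L109A) and 2872 (G44A) were called here, and in R53A 34 against 640 in that table. Its log2 fold changes correlate across genes by 0.745 (L109A) to 0.987 (Y98A) with those here.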
